A study of Arabidopsis thaliana with 4 samples.

How the data were processed

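Seeds at 22 °C and at 4 °C were represented by 2 arrays each, and the group of each array came from its title and treatment label. The values are probe set intensities that the authors deposited as linear signals, made with MAS5 per the submitters' processing notes, which give no version. On every array the 2% trimmed mean of the deposited intensity was 100, as found from the values. Background handling, detection calls and the genome build are not given in the sources used here, and scanner files were not used here. The scale was taken as linear from the values.

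Each array was multiplied so that its 2% trimmed mean was 500, a factor of about 5. The 64 control probe sets were then left out, and 15847 of the other 22746 were kept because their mean scaled signal was at least 64. Values were tested as log2(signal + 32), so that fold changes of low signals are understated. limma 3.58.1 in R 4.3.3 fitted the 4 arrays with no covariate (lmFit, eBayes with trend), the contrast was 4 °C minus 22 °C, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Signals in the text are scaled signals.

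Gene names came from the platform annotation given with the series, with symbols updated through the RefSeq gene table of assembly TAIR10.1. It paired 13513 probe sets with 1 gene and 503 with several, and 8730 were not listed; 13436 of the single-gene probe sets matched the RefSeq table. Probe sets with several genes or none are not named. A gene was represented by its single-gene probe set with the highest mean signal. Of 90 genes with more than 1 kept probe set, 13 had fold changes of opposite sign and 0 had opposite calls.

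The tests, the rule for named genes, 23 gene lists by locus and the alternatives were fixed before the data were examined. The rule takes the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold with a mean signal of at least 200 in the higher group and both 4 °C arrays on the same side of both 22 °C arrays. It adds 23 fixed genes, of which SPT was paired with a single-gene probe set and the others were not analysed here, and from each list up to 4 members past the threshold or else the member with the largest absolute value. Of 345 listed loci 61 had a single-gene probe set and 57 were kept. The 7 lists with 3 or more kept genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. A further 10 lists defined by product names were not run, since the tables used here name no products.

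The fit was tested on simulated data for this comparison, in 5 simulations of 15847 probe sets. With spreads drawn from the fitted prior, planted log2 changes of 1, 2, 4 and 6 were recovered at 0, 12, 200 and 238 of 250 probe sets each, and 24 of 474 calls were false. With spreads drawn from each probe set's own fitted variance, 85 of 691 calls were false, or 12.3%, above the nominal rate. In both, a probe set had the same spread at both temperatures, and probe sets varied independently. The real replicate differences had an SD of 1.1 at 22 °C and 0.646 at 4 °C. Unequal spreads were not simulated, so these shares are not the error rates of the real comparison. camera called 5 of 5 planted lists and 0 of 95 unchanged ones. The genes of these simulated lists varied independently, so the correlation between genes, on which the list calls below depended, was not tested.

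Alternatives were a pseudocount of 0 or 100, no filter or a filter at 200, quantile normalization, median centring, the deposited scale, eBayes without trend or with robust estimation, the replicate letter as a block, a 2-fold minimum, the mean of all probe sets of a gene, and each array left out in turn. The deposited scale differed by the same factor of about 5 on every array, while the pseudocount of 32 and the filter at 64 were unchanged. It therefore acted as a larger pseudocount and a stricter filter, not as another normalization. Groups of 2 are too small for a test of single deviating arrays.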

Results

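The series measured transcripts in seeds of Arabidopsis thaliana of the Ler-0 (Landsberg erecta) background that were kept in darkness for 96 h at 22 °C or at 4 °C. Total RNA of 4 samples was labelled with biotin and hybridised to Affymetrix arrays, with 2 arrays at each temperature, named here replicates A and B. The labels give the developmental stage of all samples as dry seeds, although they also describe the incubation. Each array gave a MAS5 signal for 22810 probe sets, of which 64 were controls. The deposited signals had medians of 31.4 and 40.8 on the 22 °C arrays A and B and of 27.1 and 28.0 on the 4 °C arrays A and B. For arrays there is no read depth, and their number limits the precision. Nothing in the labels says that the replicates came from separate seed batches, so the p-values measure only the spread between these samples, which may be technical.

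Replicates at 4 °C resembled each other more than those at 22 °C. Across the 15847 probe sets kept, which are not independent replicates, the log2 signals of the 4 °C arrays correlated with r = 0.937 and differed by over 2-fold at 1809 probe sets. The 22 °C arrays correlated with r = 0.778 and differed by over 2-fold at 5067 probe sets. The SD of the log2 difference between replicates was 0.646 at 4 °C and 1.1 at 22 °C. Between temperatures r ranged from 0.620, for 22 °C B against 4 °C A, to 0.757, for 22 °C A against 4 °C A. By rank, 22 °C A resembled 4 °C A (Spearman rho = 0.768) as much as it did 22 °C B (0.764). No arrays held identical values.

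**Figure D1:**
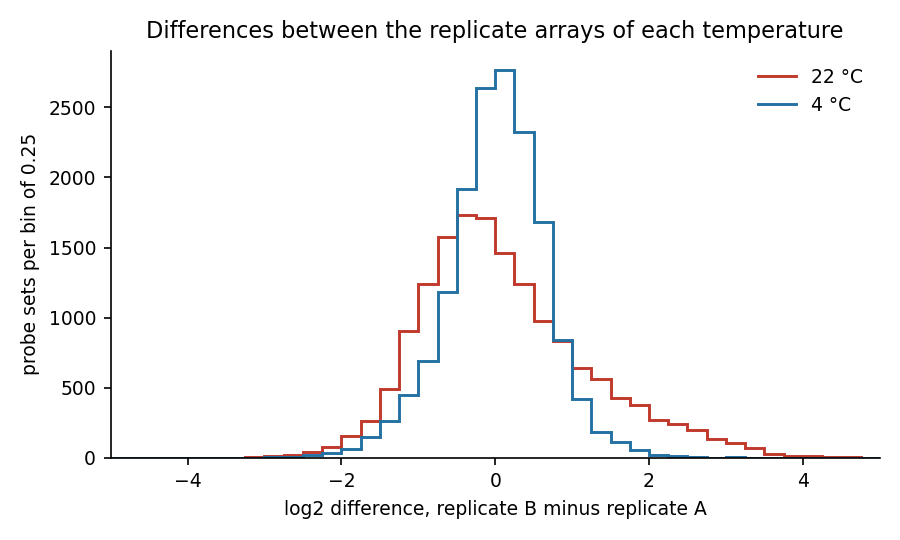
Histogram of the log2 signal difference between replicate B and replicate A (x axis, log2 units) for the 15847 probe sets kept (y axis, probe sets per bin), at 22 °C in red and 4 °C in blue. The differences at 22 °C spread wider, with an SD of 1.1 against 0.646, and trail further toward higher signal on replicate B.

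The comparison of the temperatures asks which seed transcripts differ between chilling in the dark, the condition used for stratification to release dormancy, and warm incubation in the dark. Seeds at 4 °C held more transcript of the serine carboxypeptidase-like gene scpl44, of the dehydrin gene LTI30 and of AT1G52930, a ribosome biogenesis factor. They held less of PORB, a protochlorophyllide oxidoreductase of chlorophyll synthesis, of PYK10, a beta-glucosidase of endoplasmic reticulum bodies, of LHCB4.1, a chlorophyll-binding antenna protein, and of the late embryogenesis abundant (LEA) gene AT2G42560. In the limma test, 801 of 15847 probe sets passed an adjusted p of 0.05, 430 higher and 371 lower at 4 °C. Counted with 1 single-gene probe set per gene, 238 genes were higher and 187 lower. The median log2 fold change (4 °C minus 22 °C, on signal + 32) was 2.55 among probe sets called higher and -2.97 among those called lower, and the smallest absolute value called was 1.81. Over all probe sets tested, both 4 °C arrays lay on the same side of both 22 °C arrays at 57.1%. A chance share of 33.3% holds only if all 4 arrays are interchangeable. The SD between replicates was 0.646 at 4 °C and 1.1 at 22 °C, so the shares are no test of temperature. The median over all probe sets was -0.125, against 0.0448 after quantile normalization and 0.0304 after median centring, and the fold changes below are to be read relative to it. With 1 array left out, the spread was estimated only from the pair at the other temperature. The count of calls rose without either 22 °C array and fell to almost none without either 4 °C array. It thus followed which pair gave the spread, and does not show how far the calls rest on any single array. The probe set left without 4 °C A was 257313_at, and 250109_at and 259382_s_at joined it without 4 °C B; all are unnamed here, were lower at 4 °C, and were picked out after their values were seen.

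The 10 named genes with the largest increases at 4 °C were led by scpl44, whose signal was 8555 ± 4670 at 4 °C and 160.8 ± 18 at 22 °C (SD, n = 2), a log2 fold change of 5.36 ± 0.541 (SE; limma adjusted p = 0.0273). AT1G79470, which encodes inosine monophosphate dehydrogenase of guanine nucleotide synthesis, rose by 4.11 ± 0.614 (adjusted p = 0.0317), from 113.5 ± 93.3 to 2333 ± 1050. AT5G02050, of the mitochondrial glycoprotein family, rose from 442.7 ± 8.11 to 7814 ± 1730, and AT1G52930 from 493.2 ± 147 to 7987 ± 1180, with log2 fold changes of 4.03 and 3.95. AT4G30650, of a low-temperature and salt responsive family, rose by 3.99 ± 0.774 (adjusted p = 0.0383), with 4 °C signals of 5622 on array A and 1407 on array B. The class III peroxidase gene AT2G22420 rose by 3.99, from 156.3 ± 118 to 2670 ± 528, and the AAA-type ATPase gene AT4G36580 by 3.94, from 77.7 ± 8.05 to 1669 ± 419. AT3G59670, AT5G06190 and AT1G68500 rose by 3.92, 3.69 and 3.61.

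The 10 named genes with the largest decreases had low signals on both 4 °C arrays. AT4G23670, of the polyketide cyclase and lipid transport superfamily, fell by 6.38 on the log2 scale (SE 0.675; limma adjusted p = 0.0273), from 4223 ± 3550 at 22 °C to 10.3 ± 12.5 at 4 °C (SD, n = 2). PORB fell by 6.06 (SE 0.897; adjusted p = 0.0317), with signals of 1826 and 12780 on 22 °C A and B and of 80.3 and 15.4 on 4 °C A and B. PYK10 fell by 5.83, from 9764 ± 8190 to 108.6 ± 31.8, and AT1G09310, which encodes a protein of the DUF538 family, fell by 5.89, from 6013 ± 5500 to 47.3 ± 20.5. The acid phosphatase-like genes AT5G44020 and AT1G04040 had log2 fold changes of -5.57 and -5.32, and the GDSL-type lipase gene AT3G16370 had -5.27. The methionine sulfoxide reductase gene MSRB9, AT2G32150 and AT1G62480 had log2 fold changes of -5.21, -5.21 and -5.17. Most 4 °C signals of these genes lay near background, so the pseudocount sets the size and order of their folds: with a pseudocount of 0 the log2 fold change was -8.59 for AT1G62480, -6.74 for MSRB9 and -6.21 for PYK10. All 10 had a higher signal on 22 °C B than on 22 °C A, whereas over all 371 probe sets called lower 186 did, with a median B over A ratio of 1.003. Leaving out either 4 °C array, or the filter on low signal, ended the calls of all 25 named genes that passed, while their log2 fold changes stayed between 0.753 and 1.25 times the value with all arrays. Without 22 °C A that ratio ran from 0.685 to 1.36 and without 22 °C B from 0.643 to 1.31: there AT2G32150 had a log2 fold change of -3.35 and AT1G62480 of -3.38. A pseudocount of 100 ended 8 of the 25 calls, eBayes without trend 2, and robust estimation and the deposited scale 1 each.

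**Figure D2:**
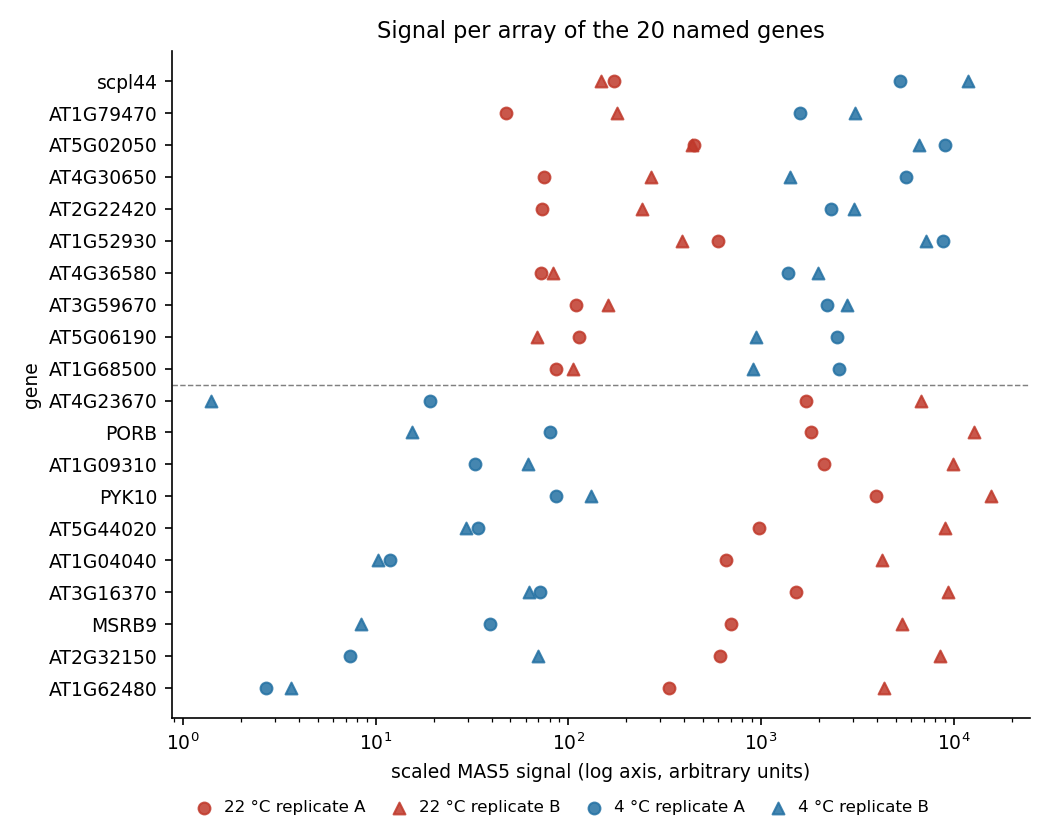
Scaled MAS5 signal (x axis, log scale, arbitrary units) of the 20 named genes with the largest fold changes (y axis) on each of the 4 arrays, with 22 °C in red, 4 °C in blue, circles for replicate A and triangles for B. The 10 genes above the dashed line were higher at 4 °C and the 10 below it lower, with no overlap between temperatures.

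Among the 23 gene lists fixed before the data were examined, LEA genes, whose products accumulate in maturing seeds, had a camera adjusted p = 0.0324 over the 7 lists tested, toward lower values at 4 °C, with a median log2 fold change of -0.994. The call was lost with an estimated correlation (adjusted p = 0.758) and with fry (adjusted p = 0.477). The list also named dehydrins, but none of these was among the genes kept. Of 17 measured members, 2 fell, 0 rose and 15 did not pass, and 6 were lower when adjusted over the list alone. AT2G42560 fell by 5.04 (limma adjusted p = 0.0273), from 6428 ± 3530 to 156.7 ± 74 (SD, n = 2), and AT3G22490 by 2.99 (adjusted p = 0.0474), from 3727 ± 3050 to 356.5 ± 21.6, a call lost without the variance trend (adjusted p = 0.0515) and with a pseudocount of 100 (0.0658). M10 had 12160 ± 1940 at 22 °C and 15030 ± 1350 at 4 °C. Members were also lower on 22 °C B than on 22 °C A at 16 of 17 genes, with a median difference of -1.71. Without 22 °C A the list's median was -0.318 and its adjusted p = 0.822, without 22 °C B they were -1.76 and 1.01e-06, and over all settings the adjusted p ranged from 1.01e-06 to 0.822.

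Tubulins, the subunits of microtubules, had a median log2 fold change of -1.60 over 7 measured genes (camera adjusted p = 0.303, and 0.758 with an estimated correlation). TUB1 fell by 4.17 (limma adjusted p = 0.0486), from 2985 ± 3280 at 22 °C to 85.9 ± 70.8 at 4 °C (SD, n = 2), 6 did not pass, and 2 were lower when adjusted over the list alone. Without 22 °C B the log2 fold change of TUB1 was -2.70. Its call was lost without the variance trend (adjusted p = 0.0541), with robust estimation (0.0527) and with a pseudocount of 100 (0.0749). TUB6 had 1427 ± 1490 and 87.5 ± 26.9, and TUA1 had 294.6 ± 105 and 703.4 ± 185. All 7 tubulins were higher on 22 °C B than on 22 °C A, by a median of 2.63. The list's median was -0.308 without 22 °C B and -2.90 without 22 °C A. It was -1.14 without 4 °C A and -2.06 without 4 °C B.

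Expansins, which loosen cell walls, and xyloglucan hydrolases had a median log2 fold change of 0.612 over 8 measured genes, of which 0 passed and 2 were higher when adjusted over the list alone (camera adjusted p = 0.344). EXPA15 had 250.6 ± 105 at 22 °C and 2115 ± 1770 at 4 °C (log2 fold change 2.68, limma adjusted p = 0.0656). It passed with a filter at 200 (adjusted p = 0.0334), median centring (0.0404) and the deposited scale (0.042). Its 4 °C signals were 863.2 on array A and 3367 on array B. All 8 were higher on 22 °C B than on 22 °C A, by a median of 1.89. The list's median was -0.286 without 22 °C A and 1.38 without 22 °C B. It was 0.99 without 4 °C A, 1.56 with a filter at 200 and 1.57 on the deposited scale.

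Of 4 measured cold response genes, LTI30 rose from 1386 ± 594 at 22 °C to 14190 ± 740 at 4 °C (SD, n = 2; log2 fold change 3.39, limma adjusted p = 0.0317) and 3 did not pass. COR15B, a chloroplast cold-regulated gene, had 34.4 ± 18.6 and 164.8 ± 92.1. The zinc finger gene STZ had 1359 ± 1300 and 196.7 ± 46.3, and the dehydrin gene COR47 had 285.4 and 4486 on 22 °C A and B against 182.6 and 150.5 on 4 °C A and B. Adjusted over the list alone, 2 were higher and 2 lower. The list's median was -0.347 while its mean was 0.025 and camera gave an upward direction (adjusted p = 0.535), so they differed in sign; the median was 0.56 without 22 °C B and -2.41 without 4 °C A. It was -2.21 with a filter at 200, -1.77 on the deposited scale, -0.128 after quantile normalization, -0.191 after median centring, -0.0588 with a pseudocount of 0 and 0.029 with no filter.

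None of the 6 measured genes of gibberellin perception and signalling passed the limma test over all genes, and 2 were lower when adjusted over the list alone; their median was -0.852 (camera adjusted p = 0.303), -1.36 without 22 °C B (0.0597) and -1.29 with a filter at 200. The receptor genes GID1A and GID1C had signals of 4463 ± 2960 and 355.5 ± 194 at 22 °C and of 1095 ± 30.6 and 80.7 ± 28.8 at 4 °C (SD, n = 2), and 4 of 6 members were lower on 22 °C B than on 22 °C A. GID1A had a log2 fold change of -1.82, but -1.09 without 22 °C A and -2.55 without 22 °C B. Of 3 measured storage protein and oleosin genes 0 passed, and 1 was lower when adjusted over the list alone (median -0.769, camera adjusted p = 0.303; -0.349 without 4 °C A and -1.19 without 4 °C B). The oleosin gene OLEO3 had 1571 ± 377 at 22 °C and 503.2 ± 219 at 4 °C. Its log2 fold change was -1.63, and -1.87 without 22 °C A. Of 4 heat shock genes 0 passed over all genes or adjusted over the list alone (median -0.652, camera adjusted p = 0.535). All 4 were lower on 22 °C B than on 22 °C A. AT5G37670 had 285.1 ± 264 at 22 °C and 56.7 ± 3.32 at 4 °C. Its log2 fold change was -1.53, but -0.558 without 22 °C A and -2.51 without 22 °C B. The median of the heat shock list was 0.161 without 22 °C A, -1.33 without 22 °C B, -0.385 without 4 °C B and -0.364 after quantile normalization.

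**Figure D3:**
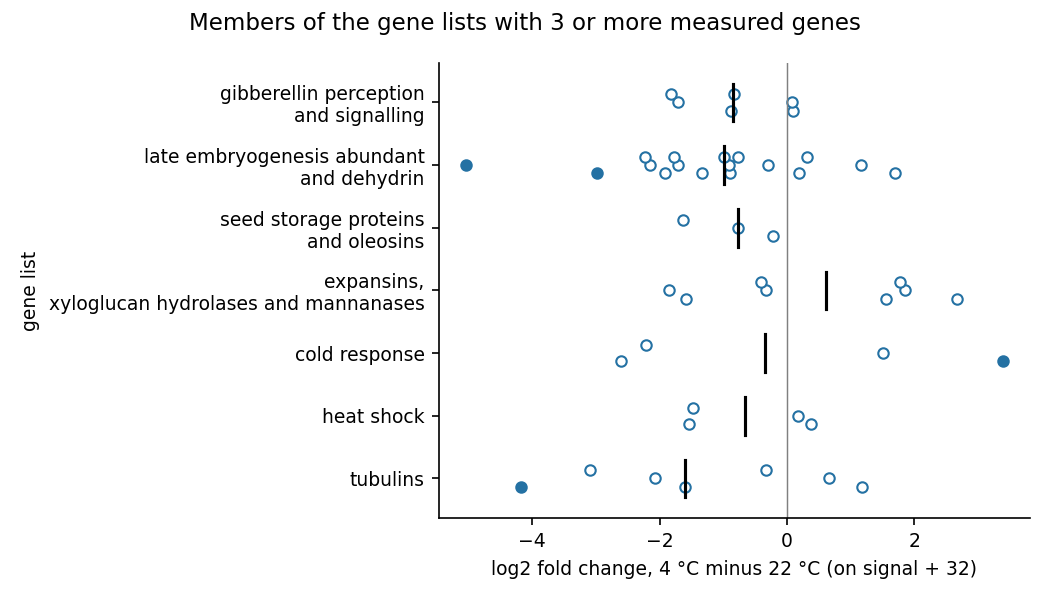
Log2 fold change (x axis, 4 °C minus 22 °C on signal + 32) of each measured gene in the 7 lists with 3 or more measured genes (y axis), filled where the gene passed an adjusted p of 0.05, with a bar at each list's median. The LEA list has its median at -0.994 and the tubulins at -1.60, and single members of most lists lie on both sides of 0.

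Other lists had 1 or 2 measured genes and no test as a list. LHCB4.1, the photosynthesis gene measured, fell from 3776 ± 83.5 at 22 °C to 252.3 ± 53 at 4 °C (SD, n = 2), a log2 fold change of -3.76 (limma adjusted p = 0.0279), with 3717 and 3835 on 22 °C A and B. The lipase gene SDP1 of storage oil breakdown had 907.5 ± 160 and 1752 ± 271, and ICL, the isocitrate lyase of the glyoxylate cycle, had 8584 ± 5190 and 14100 ± 11300. The clock gene GI had 924.3 ± 95.2 and 615.8 ± 17.1, the replication gene PRL had 170.6 ± 71.7 and 264 ± 126, and the auxin response gene IAA29 had 143.1 ± 110 and 34.9 ± 4.62. EIN3, a transcription factor of ethylene signalling, had 9049 ± 2950 and 6105 ± 574. SPT, a basic helix-loop-helix factor, had 537.8 and 1089 on 22 °C A and B and 1044 and 1000 on 4 °C A and B (log2 fold change 0.399 ± 0.512, SE; -0.0890 without 22 °C A and 0.887 without 22 °C B). Without 22 °C A the log2 fold change of IAA29 was -1.92 in place of -1.23. That of EIN3, -0.529, was -0.192 without 22 °C A and -0.867 without 22 °C B. That of PRL, 0.525, ranged from 0.0776 without 4 °C B to 0.972 without 4 °C A. With all 4 arrays, none of these except LHCB4.1 passed the limma test. Gibberellin biosynthesis and deactivation, abscisic acid biosynthesis, hydroxylation and signalling, endosperm and embryo markers, and common reference genes had no single-gene probe set. The seed coat markers had 1, which the filter on low signal left out. None of these lists was analysed here.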

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

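The values in this part were picked out after the results were seen, from control probe sets that took no part in the comparison. All 5 GAPDH control probe sets, of 19 plant controls, had both 4 °C arrays above both 22 °C arrays. The mean 4 °C signal over the mean 22 °C signal was 3.06 for the 3-prime probe set of the older series (6853 ± 2180 against 2237 ± 553, SD, n = 2), 3.25 for its 5-prime probe set (8322 ± 15 against 2564 ± 1840) and 2.51 for its middle one (12320 ± 2100 against 4911 ± 4010). In the newer series it was 2.97 for the 3-prime probe set (17970 ± 3230 against 6052 ± 5280) and 2.86 for the 5-prime one (17280 ± 1230 against 6041 ± 5080). Its size depended on the 22 °C array: the mean 4 °C signal was 3.71 to 7.75 times that of 22 °C A and 1.59 to 2.61 times that of 22 °C B, as in the newer 3-prime probe set, with 2318 on A and 9786 on B. Of 6 actin controls 4 also had both 4 °C arrays above both 22 °C arrays, with mean ratios of 1.16 to 1.28, and 3 of 5 ubiquitin controls and the 5S ribosomal RNA control had them below. Over the GAPDH probe sets the ratio ran from 1.97 to 2.71 after quantile normalization and from 3.49 to 4.48 after scaling to equal medians, with the temperatures still apart. No test was run on these controls.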

How the results depend on the processing

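Alternatives were planned unless said otherwise. Against 801 probe sets (430 higher, 371 lower), the count was 226 (139, 87) with a pseudocount of 100, 1266 (700, 566) with a filter at 200, and 2 (1, 1) with no filter, where 257313_at was lower and 261266_at higher, both unnamed here and named after their values were seen. Leaving out 1 array gave 1 to 4277 calls (0 to 1685 higher, 1 to 2676 lower), and a lone array was then assumed to vary like the other pair. With the replicate letter as a block it was 2879 (1256, 1623), and all 801 were among them. The labels do not say that the letters pair the arrays, and the replicate differences at 22 °C and 4 °C correlated across genes with r = 0.209. All 18 probe sets of added bacterial and phage spike-in transcripts were higher on A than on B at both temperatures. Shared handling by letter is therefore possible, and these data do not settle which fit is right. The block also passed the tubulin list (adjusted p = 0.0185), GID1A (0.0246), OLEO3 (0.0346) and EXPA15 (0.00174). Other settings kept the count within 1.5 times, from 683 without trend to 1128 with median centring, where 669 were higher. Lists called by camera numbered 2 with the replicate block (LEA genes and tubulins), 0 with an estimated correlation and 0 with fry, against 1. With an array left out, the lists called were not the same, and a lone array then stood for its temperature. Tubulins replaced the LEA list without 22 °C A and joined it without 4 °C B. The expansin list joined the LEA list without 22 °C B. The cold response median, -0.347, was 0.029 with no filter. With an array left out it ranged from -2.41 to 0.56, the expansin list's median from -0.286 to 1.38, that of heat shock from -1.33 to 0.161 and the log2 fold change of SPT from -0.0890 to 0.887, and the values without 22 °C A turned the last 3. Of the other alternatives for list medians, 85 kept direction and side of the threshold, 4 passed it and 1 lost it; for named genes 384 kept both, 12 passed the threshold and 87 lost it. With an array left out, the spread came only from the other pair, whose replicate difference had an SD of 0.646 at 4 °C and 1.1 at 22 °C. Apart from that, the cause of these changes was not tested. Array signals near background limit the folds of low genes.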

Other observations

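The gene lists in this part were written after single-gene values had been seen, and of the tests of explanations those on LEA genes, on the mixing ratio and on RNA integrity were set after related values were seen. Ribosome-related and proteasome genes had higher signals at 4 °C, in camera tests adjusted over 39 added lists. With fry the adjusted p was 0.133 for cytosolic ribosomal proteins and 0.12 for ribosome biogenesis factors, so those calls were lost. For proteasome subunits it was 0.0445. All 117 measured cytosolic ribosomal protein genes had a positive log2 fold change, with a median of 1.62; 23 rose and 0 fell in the limma test over all genes (camera adjusted p = 3.02e-28, and adjusted p = 0.81 with an estimated correlation). AT4G10450, of the large ribosomal subunit, rose by 3.49 ± 0.453 (SE; limma adjusted p = 0.0284), from 710.3 ± 30.2 at 22 °C to 8397 ± 1850 at 4 °C (SD, n = 2). Of 19 ribosome biogenesis factors 15 rose, with a list median of 2.70 (camera adjusted p = 2.58e-16, and adjusted p = 0.81 with an estimated correlation), and 10 of the 14 left after removing genes among the 100 most extreme probe sets rose. AT3G22660 rose from 417.7 ± 167 to 5034 ± 1540. Of 9 proteasome subunit genes 3 rose, among them AT1G79210 and RPN12a, with a list median of 1.83 (camera adjusted p = 7.79e-06, and adjusted p = 0.701 with an estimated correlation). Without 4 °C A, and without 4 °C B, 0 members of any of these lists passed, while the medians were 1.29 and 1.87 for ribosomal proteins, 2.71 and 2.57 for biogenesis factors and 1.74 and 1.80 for proteasome subunits. Without 22 °C A, and without 22 °C B, 61 and 67 ribosomal protein genes, 19 and 16 biogenesis factors and 7 and 7 proteasome genes passed, all higher.

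Plastid-encoded genes were lower at 4 °C at 65 of 69, with a median of -1.02 (camera adjusted p = 2.71e-07, and adjusted p = 0.701 with an estimated correlation), and 2 fell in the limma test: psbE by 2.54, from 4696 ± 14.7 at 22 °C to 790.3 ± 174 at 4 °C (SD, n = 2), and psbF by 2.2, from 7962 ± 1460 to 1710 ± 343. Without 4 °C A, and without 4 °C B, 0 plastid genes passed, against 19 lower without 22 °C A and 21 without 22 °C B, and without 22 °C B 15 of 69 had a positive log2 fold change. Of 35 gene families defined by shared symbols, the RNA polymerase family NRPB passed camera (6 genes, 0 called singly, median 1.29, adjusted p = 0.0213). With an estimated correlation its adjusted p was 0.81. With fry the adjusted p was 0.103 for the plastid-encoded genes and 0.392 for the NRPB family. Its median was 0.688 without 4 °C A (adjusted p = 0.218), 1.95 without 4 °C B (0.000148), 1.63 without 22 °C A (0.0146) and 1.11 without 22 °C B (0.143).

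Scaling as the whole cause of the wider differences between the 22 °C arrays is argued against by the SD of the replicate difference. At 22 °C it stayed 1.80 times that at 4 °C after quantile normalization (1.71 before). RNA breakdown was read from the 3-prime over 5-prime ratio in 6 probe set pairs of 3 control transcripts. On 22 °C B this ratio was a median of 1.12 times that on 22 °C A, and the ratio of the medians was 1.01. Single values ran from 0.466 to 1.45, so with 3 transcripts the ratio cannot exclude a difference in RNA state. The control for 25S ribosomal RNA also set 22 °C B apart, with 319.1 against 24.1 on 22 °C A. A candidate explanation is that 22 °C B was further toward germination than 22 °C A: tubulins were higher on B by a median log2 difference of 2.63, a test written before that difference was seen, and LEA genes differed by -1.71, a test set after the signals of some of them on each array were seen. Other lists were mixed on B against A: expansins were higher by 1.89 (8 of 8 genes) and storage protein and oleosin genes by 0.274 (2 of 3), ribosomal proteins differed by -0.0112 (57 of 117 higher) and ribosome biogenesis factors by -0.68 (0 of 19 higher), so this explanation stays open. Whether A was a single mixture of the same states also stays open. For 314 probe sets high on B and low at 4 °C the 75th percentile of the A over B ratio was 1.98 times the 25th (95% bootstrap interval 1.80 to 2.19). The interval resamples probe sets of 1 pair of arrays, which are not independent, so it holds no spread between samples. The probe sets were also chosen for a high signal on B, and their 4 °C level was already a median of 0.0319 of B. Tubulins and LEA genes report growing against resting tissue, so a longer or warmer incubation of 1 sample, or a sample of another stage, would give these values too and was not tested.

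On all 18 measured probe sets of added bacterial and phage spike-in transcripts the signal was higher on replicate A than on replicate B at both temperatures, by a geometric mean of 3.04 at 22 °C and 2.39 at 4 °C. Between replicate letters, with temperature as a covariate, 7 probe sets passed limma's adjusted p of 0.05 and 1616 an unadjusted p of 0.05. The control for 25S ribosomal RNA had a scaled signal of 319.1 on 22 °C B and of 24.1, 21.7 and 24.4 on 22 °C A, 4 °C A and 4 °C B.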
